A study of Mus musculus with 18 samples.

How the data were processed

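RNA from the nucleus accumbens of mice labelled Rgs9 wild type or Rgs9-2 knockout was extracted with Trizol and RNeasy Micro columns, made into TruSeq libraries and sequenced on a HiSeq sequencer, per the labels' protocols. The 18 samples were put into 6 groups of 3 by genotype, injury and treatment as the titles and characteristics give them. Per the submitters' processing notes the tools were Bowtie2 2.1.0, TopHat2 2.0.9 and Cuffdiff 2.1.1, with the builds mm9 and NCBIM37. The annotation release and the options of each tool are not given in the sources used here.

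The authors deposited 7 tables, each with 1 pair of groups and 37980 genes. The FPKM values, per the file headers, are 1 per gene and group, normalized by the authors' Cuffdiff run within each table, so levels from different tables are not on exactly 1 scale. The deposited log2 fold change is that of the second group over the first. The test statistic is a score of the authors' Cuffdiff run, signed like the fold change. The deposited p-value and q-value are Cuffdiff's, and q equals a Benjamini-Hochberg adjustment of p over the genes tested in that table. The lowest p is 5.00e-05 in every table. No table holds a value per sample, so limma on log2 values, planned for that case, was not used, and neither a refit, a block of replicates, a left-out replicate nor a regrouping of samples was possible. The design text calls the samples biological replicates. Depth per sample is unknown, and no counting interval is given. Sequencing lane is 1 per group in the titles and could not enter any test.

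A gene was called where its status was OK and its q at or below 0.05. Between 17203 and 17464 genes were tested per table. Between 20173 and 20431 genes per table had the status NOTEST, which Cuffdiff gives where alignments are too few for a test. Within every table, 331 genes had the status LOWDATA, for loci too complex or too shallowly sequenced. Another 12 had too many reads to be tested and were listed at 0, and 0 to 3 failed. Standard errors of log2 fold changes were recovered as the log2 fold change over the test statistic. A gene had no standard error here where that ratio was not above 0, where the fold change differed from the ratio of the 2 FPKM values by over 0.01, which held for 29 to 53 tested genes per table, or where the statistic gave a normal p below 1e-04 but the deposited p was above 0.05, which held for 35 to 42 per table, many of them small RNAs. That last rule was chosen after seeing the data. Of the called genes, Slc2a13 in naive mice and Peg10 after injury in mice labelled wild type had such a fold change. The middle of the test statistics was narrower than a standard normal distribution, with a standard deviation equivalent of 0.307 to 0.575, so a normal p from them is cautious for most genes. All genes of that last rule pass with a normal p from the statistic, and they make up 35 to 42 of its calls per table.

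Gene lists of pathways and cell types, 36 with 653 members of which 649 were found in the tables by symbol, the test, the threshold and the alternatives were fixed before the data were examined. For each list with at least 5 tested members a one-sided Fisher's exact test set its called genes, higher and lower apart, against all genes tested in that table, with Benjamini-Hochberg adjustment over all 476 tests, of which 36 passed. Counts adjusted over the list alone use the deposited p. Genes named in the text were chosen by a rule set beforehand: Rgs9, then per comparison the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with an FPKM of at least 1 in a group, leaving out predicted genes, pseudogenes and small RNAs. From each list up to 4 called members were named, by q and then by size of change, or up to 2 where none was called. For differences between responses, the 5 genes with the smallest p on each side were named. Not all genes so chosen are named in the text, and 1 of them is not reported here. Genes of overlaps were named after their values were seen.

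Responses were compared by the difference of their log2 fold changes over the root of the summed squared standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment, on genes with an FPKM of at least 1 in all groups. Overlaps of calls were tested with one-sided Fisher's exact tests, 24 in all for 6 pairs of responses. Fisher's exact tests of overlaps and of lists count genes as independent, so genes that move together can make their p too small. Where both responses share a group, 200 tables with no effect were simulated from the recovered standard errors, on genes with a standard error below 1, and shared calls were counted on the same genes. The shared group's part of the variance was assumed, and genes were drawn independently. Group levels were set across tables with 1 factor per table, between 0.985 and 1.02, and used only to describe. Explanations for patterns were tested against 10000 random gene sets, drawn gene by gene, and 10000 bootstrap draws, which redraw genes and not mice.

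The difference test was tested on simulated data made for the injury responses of both genotypes, with 13633 genes and 20 draws. It recovered 0.3, 3.5, 32.5 and 85 percent of true log2 differences of 0.5, 1, 2 and 4, while a test in a single table recovered 4.4, 40.4, 84.4 and 94.9 percent. False calls made up 4.86 and 5.48 percent of calls. The noise was normal and drawn from the same recovered standard errors that the tests use, so this share was fixed by the setting. In the deposited injury tables the middle of the statistics had a spread of 0.556 and 0.386 for mice labelled wild type and knockout. The recovery and false calls in the real tables may therefore differ. The alternatives were a stricter q, an FPKM filter, adjustment over all 7 tables, a normal p from the statistic, fold changes centred on their median with a normal p on genes with a recovered standard error, a minimum fold change, other list backgrounds and thresholds, other widths beside Rgs9, and other filters and pseudocounts for the responses. A normal p on genes with a recovered standard error without centring, standard errors from the deposited p, and counts without marker lists of neighbouring tissue or without genes that follow a tissue index, were added after seeing the data. Coordinates are those of the authors' tables, and a mouse reference of another build was not used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.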

Results

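Gene expression was measured by RNA sequencing in the nucleus accumbens, a ventral part of the striatum, of mice with a C57BL/6 background. The 18 samples fell into 6 groups of 3, which the series' design text calls biological replicates. Mice labelled Rgs9 wild type and mice labelled Rgs9-2 knockout were either naive or had a spared nerve injury, a lesion of branches of the sciatic nerve that gives lasting neuropathic pain. Injured mice received saline or the tricyclic antidepressant desipramine at 15 mg/kg intraperitoneally, 2 times a day. The stated purpose was to find how RGS9-2, the striatal form of a protein that shortens G protein signalling, affects gene regulation in this region under neuropathic pain and antidepressant treatment. The authors' deposited tables, 7 in all, each compare a pair of groups and give 1 FPKM value per gene and group with a log2 fold change, a test statistic, a p and a q from Cuffdiff. They hold no value per sample, so the spread between the 3 samples of a group is not seen directly. The sequencing depth of the samples is unknown here. All levels, fold changes and q values of single genes are those of the authors' deposited tables, and a value after ± is the standard error recovered from the table's test statistic. Each group was sequenced in a lane of its own, with 0 of 6 lanes holding more than 1 group, so lane and group cannot be told apart in any comparison.

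Rgs9, the gene targeted in the knockout, was higher in the groups labelled knockout in all 3 genotype comparisons of the authors' deposited tables, against the label. Its level was 120.3 to 217 FPKM, a log2 fold change of 0.85 ± 0.42, in naive mice (q = 0.0443), from the group labelled wild type to the group labelled knockout in the authors' deposited table. After injury with saline the authors' deposited table has Rgs9 (104 to 177 FPKM, log2 fold change 0.77 ± 0.27, q = 0.0170). After injury with desipramine the authors' deposited table has Rgs9 (114 to 168 FPKM, log2 fold change 0.55 ± 0.19, q = 0.00818). The gene lies on chromosome 11 from 109086668 to 109159443 in the authors' deposited tables (ENSMUSG00000020599). One value per gene includes reads from exons outside any deleted part, so it does not show whether the deleted part was transcribed. Because Rgs9 goes against the label, the groups are called labelled knockout and labelled wild type throughout, and every direction between genotypes rests on those labels. Injury and desipramine gave Rgs9 log2 fold changes in the authors' deposited tables of -0.25 ± 0.43 and 0.13 ± 0.22 in the groups labelled wild type, and of -0.32 ± 0.26 and -0.09 ± 0.25 in those labelled knockout. None of these 4 passed the test, the lowest q being 0.903 in the authors' deposited tables. Adjusted over all 7 tables, the call in naive mice was lost (adjusted p = 0.0684), and with a normal p from the test statistic all 3 were lost.

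**Figure D1:**
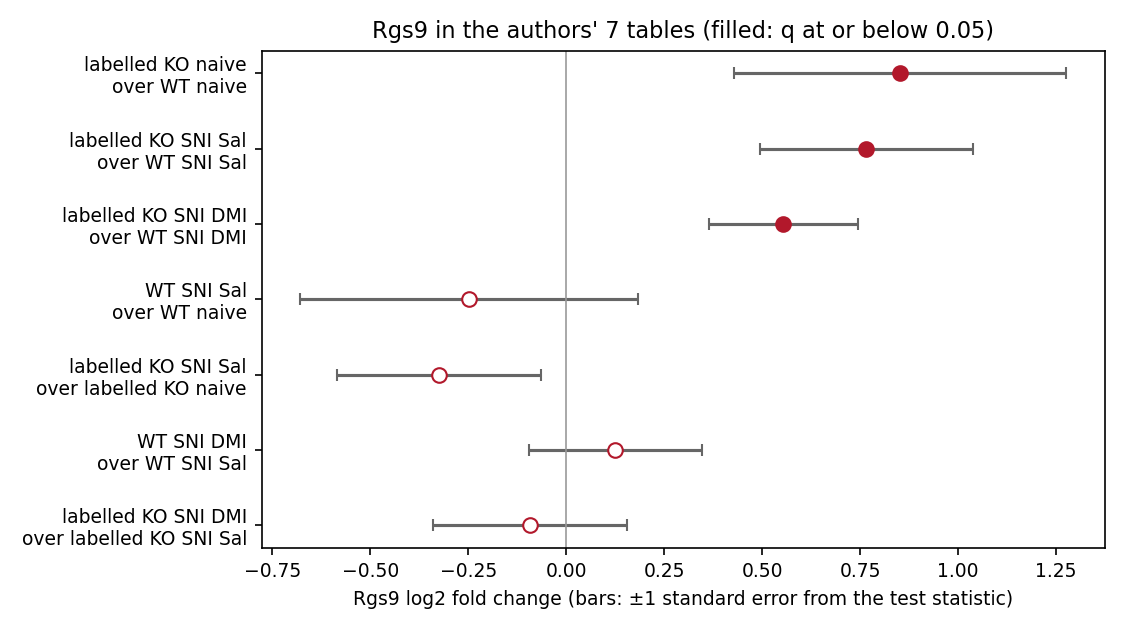
Log2 fold change of Rgs9 in each of the authors' 7 tables, with bars of 1 standard error to each side recovered from the test statistic. Rgs9 is at 0.85, 0.77 and 0.55 in the 3 comparisons of groups labelled knockout with groups labelled wild type (filled points), and the other 4 comparisons did not pass the test (open points).

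Genes beside Rgs9, which a targeted allele can carry along from its strain of origin, were not called more often than genes elsewhere. Within 10 Mb of Rgs9, 3 of 338 tested genes were called in naive mice (Myl4, Rprml and 2810008D09Rik), 1 of 342 after injury with saline (A830036E02Rik) and 2 of 338 after desipramine (Cbx8 and Krt9). One-sided Fisher's exact tests gave p of 0.866, 0.674 and 0.787, each 0.866 after adjustment over the 3 tables. These 6 genes were named after their values were seen.

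The comparison of naive mice asks how the genotypes differ without injury. Genes of cortical excitatory neurons were lower in the group labelled knockout: of 11 tested, 7 fell and none rose (list median log2 fold change -1.98, adjusted p = 5.50e-10, 7 adjusted over the list alone). Among them, in the authors' deposited table, were Slc17a7 (222 to 51.5 FPKM, log2 fold change -2.11 ± 0.52), a vesicular glutamate transporter, and the transcription factors Neurod6 (-2.26 ± 0.52) and Fezf2 (-2.22 ± 0.53). Neuropeptide genes fell too, 8 of 19 (median -0.998, adjusted p = 1.05e-09, 8 falling and 2 rising adjusted over the list alone), including Cck (149.7 to 51.9 FPKM, log2 fold change -1.53 ± 0.50), Cort (-1.98 ± 0.50), Vip (-1.67 ± 0.50) and Adcyap1 (-1.85 ± 0.57) in the authors' deposited table. Of 11 interneuron genes, 4 fell and 1 rose (median -0.05, adjusted p for the fall = 1.65e-04, 5 falling and 2 rising adjusted over the list alone). Those that fell included Pvalb (35.3 to 6.13 FPKM, log2 fold change -2.52 ± 0.52), which encodes parvalbumin, Npy (-0.998 ± 0.27) and Sst (-1.01 ± 0.29) in the authors' deposited table. Vip, Npy and Sst stand in the neuropeptide list as well. Oxt, of the same list, was at 0.157 FPKM in the naive group labelled wild type and 42.8 in that labelled knockout (log2 fold change 8.09) and was not called (q = 0.0782) in the authors' deposited table.

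Medium spiny neuron genes were higher in the naive group labelled knockout: 2 of 15 rose (adjusted p = 0.0178), 9 adjusted over the list alone, and the list median was 0.67. The called members in the authors' deposited table were Pde10a (63.4 to 149 FPKM, log2 fold change 1.23 ± 0.52) and Rasd2 (80.7 to 161 FPKM, log2 fold change 0.99 ± 0.43), a striatal small GTPase. Of 30 genes of cAMP and CREB signalling, 3 rose (median 0.25, adjusted p = 0.00306), while adjusted over the list alone 4 rose and 1 fell. The 3 were phosphodiesterases, enzymes that break down cyclic nucleotides: Pde10a, Pde1c (1.10 ± 0.46) and Pde7b (0.90 ± 0.41) in the authors' deposited table. Pde10a stands in the medium spiny neuron list as well, so these 2 list results are not separate. The smooth muscle genes Acta2 (1.28 ± 0.46) and Myh11 (1.07 ± 0.54) made up the 2 of 9 pericyte genes that rose in the authors' deposited table (median 0.44, adjusted p = 0.00712, 3 alone), a result lost with calls at q of 0.01 or less.

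Among called genes with an FPKM of at least 1 in a group, leaving out predicted genes, pseudogenes and small RNAs, the highest fold changes in the authors' deposited table of naive mice were those of Hyal1 (1.41 to 33.7 FPKM, log2 fold change 4.57 ± 0.73), a hyaluronidase, Snx31 (2.48 ± 1.91), Sytl4 (2.39 ± 0.84), the muscarinic receptor gene Chrm5 (2.101 ± 0.65) and Irs4 (1.99 ± 0.54). They were followed in the authors' deposited table by Lars2 (28.6 to 107 FPKM, log2 fold change 1.91 ± 0.64), a mitochondrial leucyl-tRNA synthetase. Hyal1 and Lars2 were high in the same groups as the small nuclear RNA 7SK, the naive and the desipramine-treated group labelled knockout, and whether library preparation plays a part was not tested. Among the same genes, the lowest in the authors' deposited table were those of the T cell receptor gene Trbc2 (-3.54 ± 0.53), Alox12b (-2.86 ± 0.71), Myoc (-2.69 ± 0.66), the immunoglobulin gene Ighg2c (-2.59 ± 0.79) and Cox8b (-2.53 ± 0.36). In all, 250 of 17358 tested genes were called, 58 higher and 192 lower. With a normal p from the test statistic 77 were called, of which 27 were among the 250 and 39 had a normal p below 1e-04 but a deposited p above 0.05. A normal p on genes with a recovered standard error, which leaves those 39 out, called 29, of which 19 were among the 250, and 28 with fold changes also centred on their median. The naive group labelled wild type stood apart from the other 5 groups on levels set across tables by 1 factor per table, since the tables were normalized separately. Its mean log2 level was 3.31 for the cortical list against 1.74 to 2.35 elsewhere, 9.12 for cytosolic ribosomal protein genes against 8.57 to 8.68, and 8.29 for nuclear respiratory chain genes against 7.76 to 7.79. The FPKM summed over genes was 648632 in this group and 526231 in the naive group labelled knockout. With injury in mice labelled wild type the sums were 660678 and 521317 for naive and injured mice. They were 527185 to 543240 in the other comparisons. The median recovered standard error was 0.520 and 0.531 in the comparisons with this group, against 0.256 to 0.336 in the others. The cause of these differences was not tested. In the comparison of naive mice the ribosomal list had a median of -0.49 with 0 of 42 genes called by Cuffdiff and 14 lower at an unadjusted p under 0.05. The respiratory chain list had a median of -0.49 with 0 of 31 called, 12 lower at an unadjusted p under 0.05 and 7 falling adjusted over the list alone. The choroid plexus list had a median of -0.76 with 0 of 14 called and 3 lower at an unadjusted p under 0.05. The red blood cell list had a median of -0.71 with 0 of 6 called, 4 lower at an unadjusted p under 0.05 and 4 falling adjusted over the list alone.

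**Figure D2:**
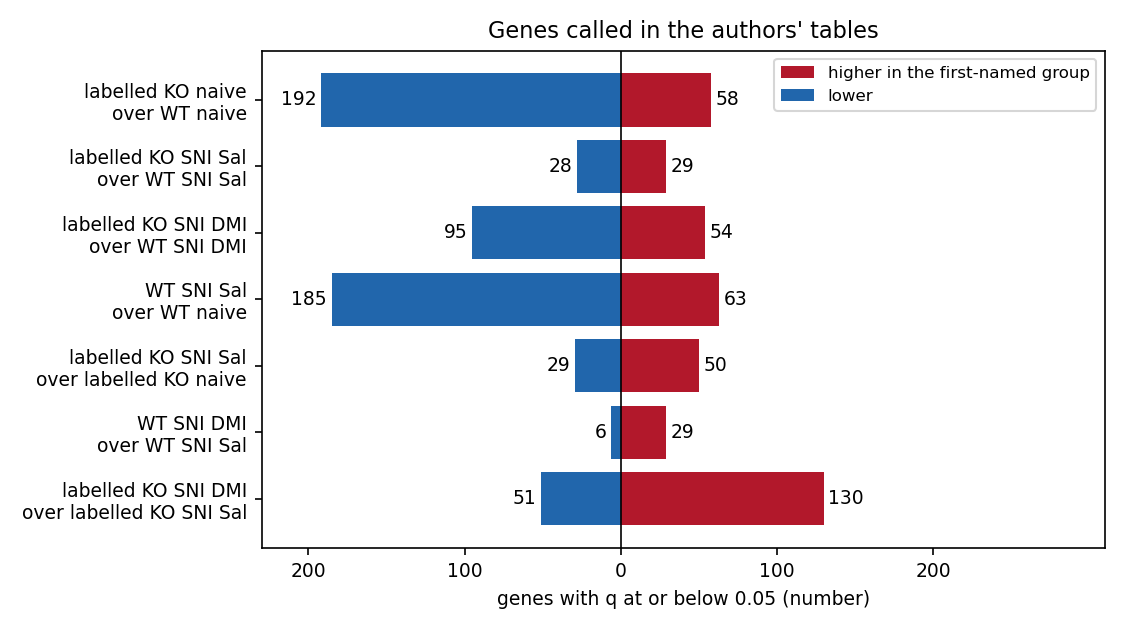
Number of genes with q at or below 0.05 in each of the authors' 7 tables, higher (right) or lower (left) in the first-named group. The comparisons that involve the naive group labelled wild type have 192 and 185 lower genes, and desipramine in injured mice labelled wild type gives 6.

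After injury with saline, choroid plexus genes were higher in the group labelled knockout than in the group labelled wild type. Of 14 tested, 5 rose and none fell (list median 1.22, adjusted p = 1.24e-09, 9 adjusted over the list alone). Among them were Ttr (99.6 to 587 FPKM, log2 fold change 2.56 ± 0.49), the thyroid hormone carrier transthyretin, the tight junction gene Cldn2 (2.55 ± 1.10), the water channel gene Aqp1 (1.70 ± 0.52) and F5 (1.61 ± 0.48) in the authors' deposited table. Meningeal and fibroblast genes had a median of 0.42, with 11 of 11 positive, 0 called by Cuffdiff, 4 higher at an unadjusted p under 0.05 and 3 rising adjusted over the list alone. Immediate-early genes, which neuronal activity induces, were higher as well: 3 of 29 rose (median 0.35, adjusted p = 5.11e-04, 9 alone), namely Nr4a1 (13.1 to 21.9 FPKM, log2 fold change 0.74 ± 0.24), Npas4 (0.71 ± 0.29) and Arc (0.68 ± 0.27) in the authors' deposited table. The mean log2 level of this list was 2.40 in the injured, saline-treated group labelled wild type, the lowest of the 6 groups, 2.72 in that labelled knockout, and 2.74 and 2.76 in the naive groups, on levels set across tables by 1 factor per table. The hypothalamic peptide genes Oxt (5.08 to 0.523 FPKM, log2 fold change -3.28 ± 0.47) and Gal (-1.64 ± 0.37) fell in the authors' deposited table, the 2 of 20 neuropeptide genes that did (median -0.13, adjusted p = 0.00801, 6 falling and 3 rising adjusted over the list alone). Oxt also stands in the list of septal, pallidal, thalamic and hypothalamic neuron genes, whose median was -0.48 with 1 of 15 called and 7 falling adjusted over the list alone (adjusted p = 0.264).

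Further genes at the extremes of the authors' deposited table for injured, saline-treated mice were Myoc (2.25 ± 0.46), Tnnt1 (2.12 ± 0.63), a troponin gene, and Kcne2 (1.74 ± 0.60) on the higher side. On the lower side in the authors' deposited table were Ccl9 (-3.21 ± 0.85), a chemokine, Irs4 (-1.61 ± 0.34), Sytl4 (-1.58 ± 0.61) and the GABA-A receptor subunit genes Gabrq (-1.45 ± 0.35) and Gabre (-1.40 ± 0.50). In total 57 of 17304 tested genes were called, 29 higher and 28 lower. A normal p on genes with a recovered standard error called 16, and as many with fold changes also centred. The ependymal list had a median of -0.67 with 0 of 8 called by Cuffdiff and 4 lower at an unadjusted p under 0.05. The cortical list had a median of 0.56 with 0 of 11 called and 3 higher at an unadjusted p under 0.05.

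With desipramine after injury, the choroid plexus difference between the groups labelled knockout and wild type covered 9 of 14 genes, all higher in the group labelled knockout (list median 2.11, adjusted p = 1.29e-17, 13 adjusted over the list alone). It included Ttr (13.6 to 411 FPKM, log2 fold change 4.92 ± 0.67), F5 (2.81 ± 0.42), Cldn2 (2.77 ± 1.24) and the folate receptor gene Folr1 (1.48 to 7.97 FPKM, log2 fold change 2.43 ± 0.65) in the authors' deposited table. Neuropeptide genes fell in 4 of 20 cases (median -0.11, adjusted p = 1.55e-04, 5 falling and 1 rising adjusted over the list alone). They were Avp (24.7 to 1.80 FPKM, log2 fold change -3.77 ± 0.32), which encodes vasopressin, Adcyap1 (-1.49 ± 0.32), Cck (81.3 to 40.5 FPKM, log2 fold change -1.005 ± 0.22) and Vip (-0.93 ± 0.27) in the authors' deposited table. Cortical neuron genes fell in 3 of 11 cases (median -0.29, adjusted p = 7.58e-04, 5 alone), with Slc17a7 (88.3 to 41.5 FPKM, log2 fold change -1.09 ± 0.20), Neurod2 (-0.93 ± 0.26) and Emx1 (-1.10 ± 0.47) in the authors' deposited table. Of 11 interneuron genes 2 fell (median -0.07, adjusted p = 0.0228, 2 alone), Vip and Pvalb (-0.90 ± 0.28) in the authors' deposited table. Of 15 septal and hypothalamic genes 2 fell (adjusted p = 0.0405, 2 alone), Avp and Slc17a6 (-0.64 ± 0.20), in the authors' deposited table. The median of that last list was 0.00 and its mean -0.31. Both the interneuron and the septal result were lost with calls at a deposited p of 0.01 or less.

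Among the other genes, Hyal1 (2.00 to 15.6 FPKM, log2 fold change 2.96 ± 0.47), Lars2 (31.3 to 184 FPKM, log2 fold change 2.56 ± 0.36) and Prss56 (2.13 ± 0.40) were higher in the authors' deposited table. In it Igfn1 (-3.60 ± 1.29), the vesicular zinc transporter gene Slc30a3 (-2.38 ± 0.25) and the Polycomb gene Cbx8 (60.9 to 15.1 FPKM, log2 fold change -2.01 ± 0.13) were lower in the authors' deposited table. The test called 149 of 17340 genes, 54 higher and 95 lower. A normal p from the test statistic called 86, of which 41 had a deposited p above 0.05. On genes with a recovered standard error it called 39, of which 19 were higher and 20 lower, with fold changes centred or not. Oligodendrocyte genes had a median of 0.21, with 13 of 13 positive, 0 called by Cuffdiff and 5 higher at an unadjusted p under 0.05. The ependymal list had a median of 0.68, with 1 of 8 called and 6 rising adjusted over the list alone (adjusted p = 0.264).

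**Figure D3:**
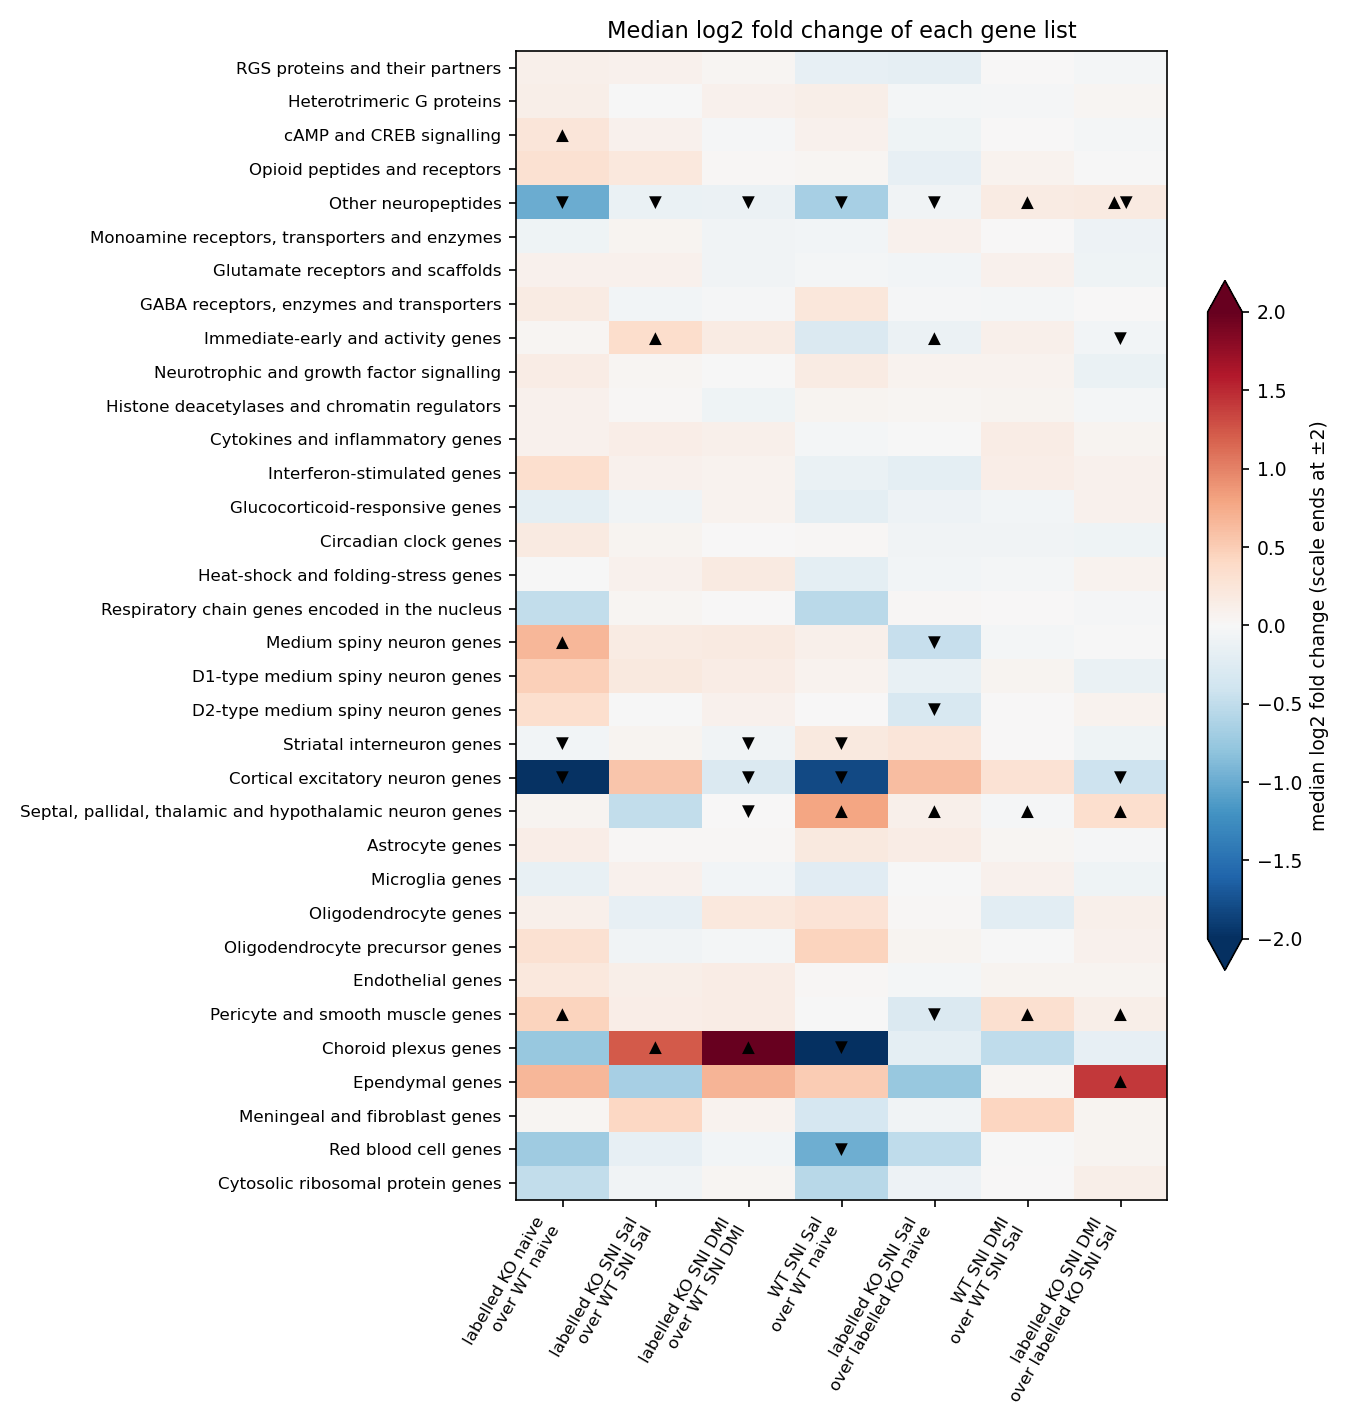
Median log2 fold change of each gene list with at least 5 tested members (1 line each) in the 7 comparisons, with the colour scale ending at 2 on either side. Triangles mark lists with more higher (up) or lower (down) calls than other genes at an adjusted p of 0.05 or less, and choroid plexus genes range from -2.62 to 2.11.

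Injury in mice labelled wild type, the saline-treated injured group against the naive group, asks how this region differs after nerve injury. The labels mention no injection of naive mice, so injury and repeated saline injection cannot be separated in either comparison of an injured with a naive group. Choroid plexus genes fell, 10 of 14 (median -2.62, adjusted p = 3.20e-15, 10 alone), with Ttr (1384 to 98.5 FPKM, log2 fold change -3.81 ± 0.80), Aqp1 (-3.23 ± 0.67), Folr1 (24.97 to 3.67 FPKM, log2 fold change -2.77 ± 0.50) and F5 (-2.68 ± 0.68) in the authors' deposited table. The meningeal and fibroblast list had a median of -0.33, with 2 of 11 positive, 1 called lower (adjusted p = 0.741), 3 lower at an unadjusted p under 0.05 and 2 falling adjusted over the list alone. Cortical neuron genes fell in 7 of 11 cases (median -1.80, adjusted p = 5.27e-10, 7 alone), among them Slc17a7 (225 to 50.7 FPKM, log2 fold change -2.15 ± 0.61), Neurod6 (-2.02 ± 0.56) and Tbr1 (-1.84 ± 0.53) in the authors' deposited table. Of 20 neuropeptide genes 4 fell (median -0.66, adjusted p = 0.00145, 9 falling and 2 rising adjusted over the list alone). They were Cort (-1.87 ± 0.58), Cck (152 to 44.3 FPKM, log2 fold change -1.78 ± 0.58), Npy (-1.25 ± 0.28) and Sst (-1.15 ± 0.31) in the authors' deposited table. Haemoglobin genes made up the 3 of 6 red blood cell genes that fell (median -0.98, adjusted p = 7.25e-04, 5 alone), led by Hba-a2 (-1.32 ± 0.51) and Hba-a1 (-1.23 ± 0.49) in the authors' deposited table. Genes of septal, pallidal, thalamic and hypothalamic neurons rose in 2 of 15 cases (median 0.79, adjusted p = 0.0200, 6 alone), Dlk1 (1.57 ± 0.55) and Calcr (1.42 ± 0.66) in the authors' deposited table. With calls at q of 0.01 or less this result was lost.

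Interneuron genes fell in 3 of 11 cases and rose in 1 (adjusted p for the fall = 0.00375, 4 falling and 2 rising adjusted over the list alone), although the list median was 0.19 and its mean -0.15. The 3 were Npy, Sst and Pvalb (-1.26 ± 0.50), and the 1 that rose was the choline transporter gene Slc5a7 (0.93 ± 0.42), in the authors' deposited table. Immediate-early genes had a median of -0.29, with 1 of 29 called lower, 9 lower at an unadjusted p under 0.05 and 5 falling adjusted over the list alone. Of 31 nuclear respiratory chain genes 3 were called lower, Ndufa2 (-1.07 ± 0.51), Uqcrq (-0.96 ± 0.47) and Atp5j2 (-1.06 ± 0.50) in the authors' deposited table, and the list missed the threshold (median -0.54, adjusted p = 0.0544, 10 alone). Among called genes with an FPKM of at least 1 in a group, leaving out predicted genes, pseudogenes and small RNAs, the highest fold changes in the authors' deposited table were those of Sytl4 (2.77 ± 0.87), Irs4 (2.61 ± 0.56), Gabre (2.55 ± 0.70), Dgkk (2.29 ± 0.53) and Gabrq (2.24 ± 0.68). Oxt had a log2 fold change of 4.97 and was not called (q = 0.0643) in the authors' deposited table. Of 17464 tested genes 248 were called, 63 higher and 185 lower. A normal p from the test statistic called 86, of which 38 had a normal p below 1e-04 but a deposited p above 0.05. On genes with a recovered standard error it called 32, and 26 with fold changes also centred. The naive group labelled wild type is the same as in the genotype comparison of naive mice, so both comparisons share what sets it apart. The ribosomal protein list had a median of -0.55 here with 1 of 42 called and 13 falling adjusted over the list alone.

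After injury in mice labelled knockout, genes of D2-type medium spiny neurons fell, 3 of 8 (median -0.32, adjusted p = 1.14e-05, 3 alone). These were the dopamine receptor gene Drd2 (82.0 to 56.2 FPKM, log2 fold change -0.55 ± 0.24), the adenosine receptor gene Adora2a (-0.54 ± 0.22) and Gpr6 (-0.60 ± 0.20) in the authors' deposited table. The D1-type list had a median of -0.15, with 0 of 10 called by Cuffdiff and 3 falling adjusted over the list alone. With calls at a deposited p of 0.01 or less it passed as well (adjusted p = 0.00101), so the fall was not particular to D2-type genes. Of 15 general medium spiny neuron genes 2 fell (median -0.46, adjusted p = 0.00541, 9 alone), Tmem158 (154 to 99.6 FPKM, log2 fold change -0.63 ± 0.18) and Rasd2 (-0.58 ± 0.26) in the authors' deposited table. The naive group labelled knockout stood apart on these lists, with the highest mean log2 level of the 6 groups, 7.45 for the general list with 6.79 as the lowest, and 5.30 for the D2-type list against 4.92 to 5.01 in the other 5, on levels set across tables by 1 factor per table. In mice labelled wild type the D2-type list had a median of 0.01 with injury, with 0 of 8 called by Cuffdiff and 0 at an unadjusted p under 0.05. Oxt (43.3 to 0.517 FPKM, log2 fold change -6.39 ± 0.44) had the lowest fold change of the genes named from the authors' deposited table. With Gal (-1.58 ± 0.40) it made up the 2 of 18 neuropeptide genes that fell in the authors' deposited table, while Adcyap1 (1.37 ± 0.41) rose (list median -0.08, adjusted p for the fall = 0.00728, 3 falling and 4 rising adjusted over the list alone). The immediate-early genes Npas4 (3.50 to 6.94 FPKM, log2 fold change 0.99 ± 0.29) and Fos (0.90 ± 0.37) rose and Egr3 (-0.64 ± 0.25) fell in the authors' deposited table. With 2 of 29 higher, the list had an adjusted p = 0.0423, 3 rising and 1 falling adjusted over the list alone, and a median of -0.11. Smooth muscle genes fell, 2 of 9 pericyte genes (median -0.30, adjusted p = 0.00233, 2 alone), Acta2 (-1.32 ± 0.30) and Myh11 (-0.90 ± 0.35) in the authors' deposited table.

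In the septal and hypothalamic list Gbx1 (1.21 ± 0.36) and Slc17a6 (0.97 ± 0.29), a vesicular glutamate transporter gene, rose in the authors' deposited table after injury in mice labelled knockout (2 of 15 higher, adjusted p = 0.0139, 2 rising and 1 falling adjusted over the list alone). Oxt fell in the same list, whose median was 0.10 and mean -0.33. For this comparison the septal result and that of the neuropeptide genes were lost with calls at a deposited p of 0.01 or less. The red blood cell list had a median of -0.51, with 0 of 6 called by Cuffdiff, 4 lower at an unadjusted p under 0.05 and 4 falling adjusted over the list alone. Other genes at the extremes of the authors' deposited table were Myoc (2.90 ± 0.50), the neurotrophin receptor gene Ngfr (1.45 to 5.62 FPKM, log2 fold change 1.95 ± 0.34), Tnnt1 (1.90 ± 0.61), Gnrh1 (1.77 ± 0.34) and Pvalb (1.52 ± 0.36) among the higher. Among the lower in the authors' deposited table were Hyal1 (33.7 to 1.83 FPKM, log2 fold change -4.20 ± 0.41) and Lars2 (107 to 19.2 FPKM, log2 fold change -2.48 ± 0.40). The test called 79 of 17203 genes, 50 higher and 29 lower. A normal p on genes with a recovered standard error called 20, of which 10 were higher and 10 lower, with fold changes centred or not. The cortical list had a median of 0.61, with 1 of 11 called and 8 rising adjusted over the list alone (adjusted p = 0.310). The ependymal list had a median of -0.76, with 1 of 8 called and 4 falling adjusted over the list alone (adjusted p = 0.168).

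Desipramine in injured mice labelled wild type asks how the region differs with the antidepressant after injury. Neuropeptide genes rose, 4 of 20 (median 0.17, adjusted p = 1.79e-06, 5 alone): Avp (0.801 to 24.7 FPKM, log2 fold change 4.95 ± 0.36), Oxt (5.13 to 21.8 FPKM, log2 fold change 2.09 ± 0.30), Cck (0.86 ± 0.30) and Adcyap1 (0.84 ± 0.32) in the authors' deposited table. Avp and Oxt were also the 2 of 15 septal and hypothalamic genes that rose (adjusted p = 0.00541, 2 alone), in a list with a median of -0.02 and a mean of 0.45. That list marks neighbouring tissue, and Oxt was higher still in the naive group labelled knockout, which had no drug. Whether such tissue carried along plays a part in the levels of Avp and Oxt was not tested in any comparison. The smooth muscle genes Acta2 (4.70 to 10.3 FPKM, log2 fold change 1.13 ± 0.27) and Myh11 (0.93 ± 0.32) rose in the authors' deposited table (2 of 9 pericyte genes, median 0.31, adjusted p = 0.00233, 2 alone). Meningeal and fibroblast genes had a median of 0.44, with 11 of 11 positive, 1 called (adjusted p = 0.207) and 4 rising adjusted over the list alone. Others that rose in the authors' deposited table were Igfn1 (3.12 ± 1.25), Myoc (1.74 ± 0.42), Slc30a3 (5.30 to 14.8 FPKM, log2 fold change 1.49 ± 0.30) and the retinoic acid hydroxylase gene Cyp26b1 (1.46 ± 0.38). Among those that fell in the authors' deposited table were Ccl9 (12.9 to 1.10 FPKM, log2 fold change -3.55 ± 0.84) and the gonadotropin-releasing hormone gene Gnrh1 (-1.46 ± 0.28). Of 17316 tested genes 35 were called, 29 higher and 6 lower. A normal p from the test statistic gave 54, of which 39 had a deposited p above 0.05. On genes with a recovered standard error it gave 11, of which 8 were higher and 3 lower, with fold changes centred or not. Oligodendrocyte genes had a median of -0.22, with 0 of 13 positive, 0 called by Cuffdiff and 2 lower at an unadjusted p under 0.05. The choroid plexus list had a median of -0.51, with 0 of 13 called by Cuffdiff, 6 lower at an unadjusted p under 0.05 and 6 falling adjusted over the list alone. The cortical list had a median of 0.28, with Slc17a7 (0.78, q = 0.0495) called in the authors' deposited table.

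With desipramine in injured mice labelled knockout, ependymal genes were higher, most of which serve the motile cilia of the ventricle wall: 6 of 8 rose (median 1.42, adjusted p = 5.27e-10, 7 alone). Among them were Tmem212 (1.61 ± 0.35), Ccdc153 (1.55 ± 0.31), Dynlrb2 (1.495 ± 0.28) and Foxj1 (1.05 ± 0.28), a transcription factor of motile cilia, in the authors' deposited table. On levels set across tables by 1 factor per table, the saline-treated reference group had the lowest ependymal mean log2 level of the 6 groups, 1.66. It was 1.84 to 2.36 in the wild type and naive groups and 2.94 with desipramine in mice labelled knockout. The ependymal list marks neighbouring tissue, and whether such tissue carried along plays a part was not tested. Neuropeptide genes went both ways: 5 of 19 rose, Oxt (0.523 to 14.8 FPKM, log2 fold change 4.82 ± 0.43), Avp (2.52 ± 0.53) and Gal (1.93 ± 0.36) in the authors' deposited table among them (list median 0.17, adjusted p = 1.14e-05). Another 2 fell (adjusted p = 0.0210), with 7 rising and 4 falling adjusted over the list alone. Of 29 immediate-early genes 3 fell (list median -0.06 with 12 of 29 positive and 2 higher at an unadjusted p under 0.05, adjusted p = 0.00221, 4 alone): Npas4 (7.03 to 3.81 FPKM, log2 fold change -0.88 ± 0.27), Arc (-0.52 ± 0.24) and Fos (-0.79 ± 0.36) in the authors' deposited table. Cortical neuron genes fell too, 3 of 11 (median -0.42, adjusted p = 1.55e-04, 4 alone), with Slc17a7 (81.9 to 41.1 FPKM, log2 fold change -0.996 ± 0.30), Neurod2 (-0.83 ± 0.33) and Emx1 (-1.15 ± 0.56) in the authors' deposited table, a result lost with calls at q of 0.01 or less. Of 15 septal and hypothalamic genes 3 rose (median 0.34, adjusted p = 0.00375, 6 rising and 1 falling adjusted over the list alone), Oxt, Avp and Trpc4 (0.67 ± 0.27) in the authors' deposited table. Of 9 pericyte genes 2 rose (median 0.12, adjusted p = 0.0273, 2 alone), Acta2 (1.16 ± 0.28) and Myh11 (0.70 ± 0.33), in the authors' deposited table. That pericyte result was lost with calls at a deposited p of 0.01 or less.

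Besides these, Lars2 (19.5 to 182 FPKM, log2 fold change 3.23 ± 0.45), Hyal1 (1.86 to 15.5 FPKM, log2 fold change 3.06 ± 0.40) and Sytl4 (1.94 ± 0.58) rose with desipramine in mice labelled knockout in the authors' deposited table. The genes Cbx8 (99.6 to 15.0 FPKM, log2 fold change -2.73 ± 0.15), Tnnt1 (-2.17 ± 0.59) and Gnrh1 (-2.13 ± 0.35) fell in the authors' deposited table. The test called 181 of 17304 genes, 130 higher and 51 lower. A normal p from the test statistic called 78, of which 41 had a deposited p above 0.05. On genes with a recovered standard error it called 27, and 28 with fold changes also centred.

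**Figure D4:**
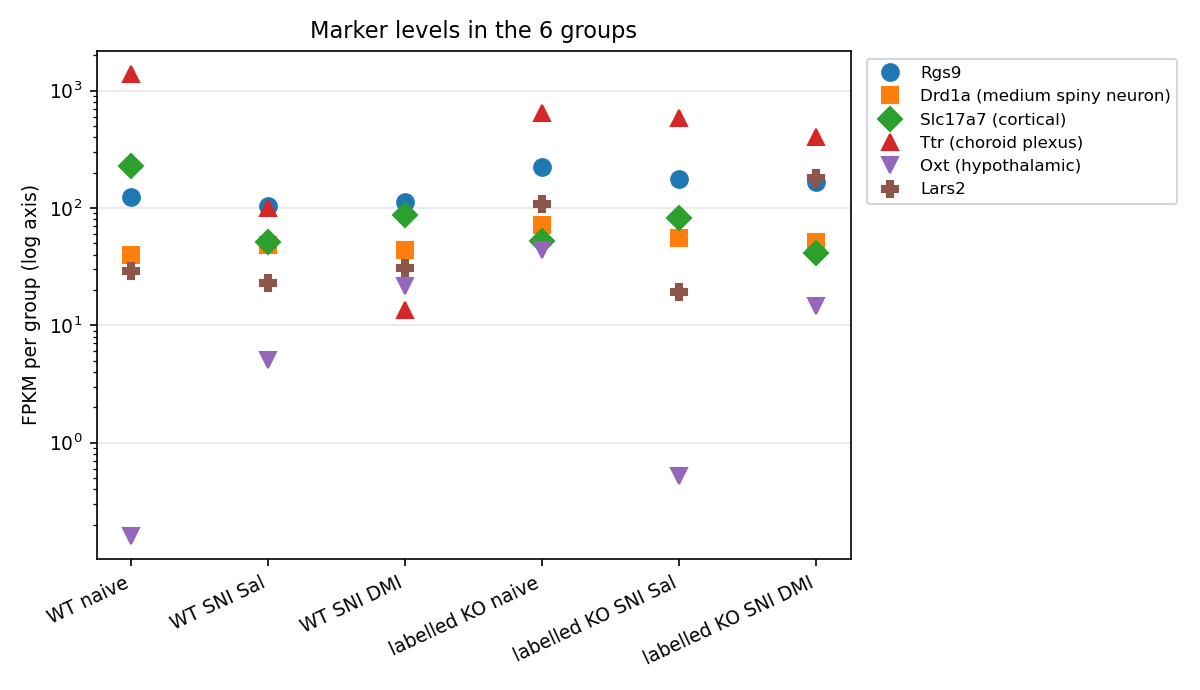
FPKM of 6 genes in the 6 groups (log axis), 1 value per group with no error, set across the separately normalized tables by 1 factor per table. Ttr runs from 13.4 to 1390, Oxt from 0.161 to 43.7 and Rgs9 from 104 to 221.5.

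The injury response in mice labelled wild type was then set against that in mice labelled knockout, which share no sample. Over 13725 genes the log2 fold changes had a Pearson correlation of 0.0484 and a Spearman correlation of 0.0825, across genes, which are not independent replicates. The median recovered standard errors, 0.531 and 0.321 for wild type and knockout labels, exceeded the standard deviations of the log2 fold changes, 0.399 and 0.239. Noise of that size can pull a correlation towards 0, so a low value does not show that responses were unlike. The same held in the other comparisons and limits the low correlations given below. Of 178 genes that fell in the groups labelled wild type and 50 that rose in those labelled knockout, 7 were the same: Fezf2, Myoc, Necab3, Nov, Nrn1, Pvalb and Slc30a3. Independent lists would share 0.524 (one-sided Fisher's exact p = 8.47e-07, adjusted over 24 overlaps 2.26e-06). Gm11942, Prr7 and RP23-381B19.7.1 fell in both responses (0.304 for independent lists, Fisher's exact p = 0.00339, adjusted 0.00740). The responses differed in 18 of 13633 genes by the test of the difference itself, 13 higher and 5 lower in the response of mice labelled knockout. The cortical list genes Slc17a7, Neurod6 and Fezf2 were among those higher. The naive group labelled wild type, which stood apart on that list, is part of this contrast. Whether cortical tissue plays a part in these differences was not tested. Pvalb moved by -1.26 and 1.52 in the authors' deposited tables for wild type and knockout labels (difference 2.78 ± 0.62, adjusted p = 0.0111), and Cox8b by -2.45 and 1.03 (3.48 ± 0.48, adjusted p = 1.28e-09). Gal moved by 1.44 and -1.58 (-3.02 ± 0.66, adjusted p = 0.0111), and Hyal1 by 0.40 and -4.20 (-4.60 ± 1.07, adjusted p = 0.0183) in the authors' deposited tables. With standard errors taken from the deposited p instead, 91 genes differed, 12 of them among the 18. The same contrast read as the genotype difference in naive against injured, saline-treated mice gave 22 genes, including all 18.

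**Figure D5:**
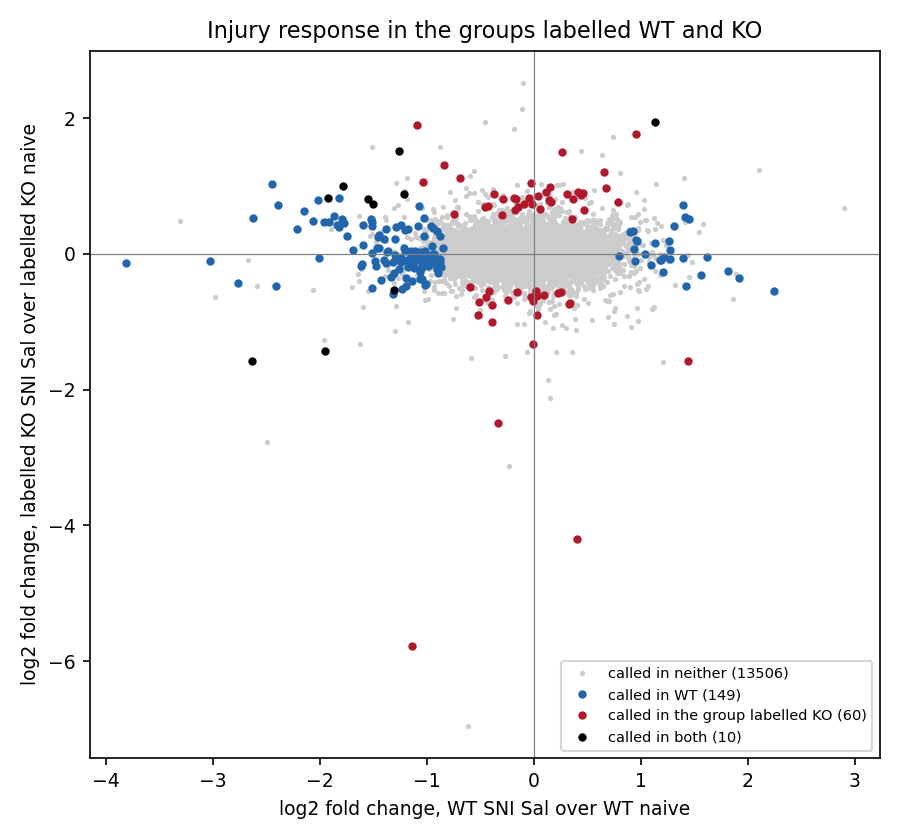
Log2 fold change with injury in mice labelled wild type (x axis) and labelled knockout (y axis), 1 point per gene with an FPKM of at least 1 in all 4 groups. Of 13725 genes, 149 were called in the groups labelled wild type alone, 60 in those labelled knockout alone and 10 in both, and the points scatter around both axes.

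The desipramine responses of the 2 genotypes had correlations of -0.0634 (Pearson) and -0.0827 (Spearman) over 13903 genes. Of the 27 genes that rose in mice labelled wild type, 7 also rose among the 127 in mice labelled knockout: Acta2, Avp, Gm11942, Gm6768, Myh11, Nr2f2 and Oxt (0.202 for independent lists, Fisher's exact p = 8.58e-10, adjusted 2.94e-09). Another 7 fell among the 51 in mice labelled knockout: Adcyap1, Cck, Myoc, Nrn1, Rtn4r, Slc17a7 and Slc30a3 (0.0809 for independent lists, Fisher's exact p = 1.20e-12, adjusted 5.77e-12). Gnrh1 fell in both (0.0180 for independent lists, Fisher's exact p = 0.0179, adjusted 0.0330). The difference itself passed the test for 20 of 13827 genes, 7 higher and 13 lower in the response of mice labelled knockout. Slc17a7, of the cortical list, was among those lower, and whether cortical tissue plays a part was not tested. Slc30a3 moved by 1.49 and -1.39 in the authors' deposited tables (difference -2.87 ± 0.45, adjusted p = 1.19e-06), and the neuritin gene Nrn1 by 0.97 and -0.68 (-1.65 ± 0.37, adjusted p = 0.0159). Irs4 moved by -0.28 and 1.59 (1.87 ± 0.40, adjusted p = 0.00631), and the cilia gene Dynlrb2 by -0.23 and 1.495 (1.72 ± 0.39, adjusted p = 0.0159) in the authors' deposited tables. With standard errors from the deposited p, 44 genes differed, 12 of them among the 20. Read as the genotype difference after saline against that after desipramine, the contrast gave 18 genes, 16 of them among the 20.

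The genotype differences in naive and in injured, saline-treated mice had a Pearson correlation of 0.0145 over 13721 genes. Ppp1r16b and Rgs9 were called higher in both (0.0939 for independent lists, Fisher's exact p = 0.00395, adjusted 0.00791). Dgkk, Gabre, Gabrq, Gm7120, Irs4 and Sytl4 were higher in the naive and lower in the injured group labelled knockout (0.0874 for independent lists, Fisher's exact p = 2.45e-10, adjusted 9.79e-10). The genotype differences after saline and after desipramine correlated at 0.0239 over 13899 genes. They shared 10 higher genes of 29 and 50 (0.0851 for independent lists, Fisher's exact p = 3.49e-19, adjusted 2.79e-18), though the test counts genes that move together as independent. These were the choroid plexus list genes Aqp1, Cldn2, F5, Kl and Ttr, with 1500015O10Rik, Car12, Kcne2, Ppp1r16b and Rgs9. The lower genes Agt, Aldh7a1, Cdhr1, Gm11942 and Gm6768 were shared as well (0.147 for independent lists, Fisher's exact p = 3.19e-07, adjusted 9.58e-07). In opposite directions, Col11a1, Myoc and Otof were higher after saline and lower after desipramine (0.158 for independent lists, Fisher's exact p = 5.19e-04, adjusted 0.00125).

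The injury and desipramine responses within a genotype share the injured, saline-treated group, and went in opposite directions across genes. Their Pearson correlation was -0.415 over 13853 genes in mice labelled wild type and -0.557 over 13885 genes in mice labelled knockout. In mice labelled wild type, 14 genes fell with injury and rose with desipramine, among them Cck, Myoc, Nrn1, Slc17a7 and Slc30a3. In mice labelled knockout, 21 rose and then fell, such as Fos, Gnrh1, Ngfr, Npas4 and Pvalb, and 12 fell and then rose, such as Gal, Hyal1, Irs4, Lars2 and Oxt. One gene, Gm7120, rose with injury and fell with desipramine in mice labelled wild type. Independent lists would share 0.286, 0.149 and 0.215 genes where 14, 21 and 12 were shared. Simulated tables with no effect but a shared group were made for genes with a standard error under 1. Among these, 10, 18 and 11 were shared, against a mean of 1.27, 3.21 and 3.07 simulated and a highest of 6, 8 and 7. The simulation assumed the shared group's part of the variance and drew genes independently. With a larger part, or with genes that move together, more could be shared, so these counts alone do not show an excess. On the same genes the correlations were -0.436 and -0.561 against -0.276 and -0.472 simulated. The covariances were -0.0238 and -0.0239, against -0.0475 and -0.0663 simulated from the standard errors as recovered, and -0.0120 and -0.00990 with the standard errors scaled to the spread of the middle of the statistics. The sign of the excess thus depends on that scale, and part of the opposite movement may come from the shared group, which 1 value per group does not allow to be split. A test of the difference that leaves out the covariance from the shared group gave 32 and 46 genes, and 180 and 161 with standard errors from the deposited p.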

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

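The tests of a difference between responses were planned, except that with standard errors from the deposited p. Of the tests of explanations in this part, those of cortical tissue, of a lower share of medium spiny neurons in the naive group labelled wild type and of the lane were set before their result was seen, and all others after. Genotype directions rest on labels that Rgs9 goes against. Differences are the response of mice labelled knockout less that of mice labelled wild type, in log2.

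The responses to injury differed between the genotype labels in 18 genes and those to desipramine in 20, by a test of the difference itself. Cortical list genes were among both: Slc17a7, Neurod6 and Fezf2 for injury, and Slc17a7 for desipramine. They were picked out after their values were seen. The injury contrast holds the naive group labelled wild type, whose cortical list level was the highest. Whether cortical tissue plays a part in these differences was not tested. For injury the difference was 3.48 for Cox8b, 2.92 for the pseudogene Rpsa-ps10, 1.07 for 2010107E04Rik, 2.78 for Pvalb and 1.31 for the G protein gene Gng13. It was -1.98 for Alox5ap, -4.64 for 7SK, -3.02 for Gal, -4.60 for Hyal1 and -1.27 for Scarna13. For desipramine it was 2.78 for 7SK, 2.81 for Lars2, 1.87 for Irs4, 1.72 for Dynlrb2 and 1.73 for Il17rc. It was -2.87 for Slc30a3, -1.52 for Rpsa-ps10, -0.71 for SNORA42, -1.65 for Nrn1 and -1.87 for A830036E02Rik. Rpsa-ps10, 7SK, Scarna13 and SNORA42 have near-identical copies or are small RNAs, so their values are uncertain. With standard errors from the deposited p, 2010107E04Rik, Gng13, 7SK and Scarna13 lost the call for injury and 7SK, Lars2, Il17rc and SNORA42 that for desipramine.

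The 192 genes lower in the naive group labelled knockout than in the naive group labelled wild type were the largest set of calls in 1 direction among the 7 comparisons. A genotype difference present in every condition would put the same genes below 0 after injury as well. Their median was 0.14 after injury with saline (95% bootstrap interval over genes 0.05 to 0.20) and -0.33 with desipramine. The saline direction goes against that explanation. The interval redraws genes and not mice, so it leaves out the spread between samples and does not exclude it. A lower share of medium spiny neurons in the samples labelled wild type, with all other cell types raised alike, is argued against: the lowest median of the astrocyte, oligodendrocyte, microglia and endothelial lists was -0.14, above the upper quartile of the cortical list, -1.17. More cortical tissue in the naive samples labelled wild type is a candidate explanation. Over the 4 groups outside the comparison, 172 of these genes had a median correlation of 0.647 with the cortical index. The upper bound for random gene sets was 0.220. The correlation rests on 4 values per gene, and the random sets were drawn gene by gene. Other sets of genes that move together could also pass, so it does not single out tissue as the cause. The naive group labelled wild type also had the highest mean levels of ribosomal protein and respiratory chain genes, and the highest summed FPKM. Whether more cortical tissue would give these was not tested. Slc17a7, itself among the called genes, stood at 226 FPKM against 40.9 to 87.2 in the other groups. Of the 11 cortical genes 8 had an FPKM of at least 1 in every group and 0 stand in another list, and lane cannot be told apart from group because 0 lanes held more than 1, so lane stays open, as does a genotype difference confined to naive mice, which was not tested.

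Rgs9 was higher in the groups labelled knockout in 3 of 3 genotype tables. Loss of its mRNA in either genotype is argued against by the ratio of the lower to the higher level, 0.554 in naive mice, 0.588 after saline and 0.681 after desipramine, although a deletion of part of the gene that leaves the rest transcribed stays open. More medium spiny neuron RNA as the whole cause is argued against after injury, where 0 of the 15 other list genes rose as much as Rgs9 in either table and the highest log2 fold changes were 0.34 and 0.29. In naive mice 4 of 15 rose as much, with a list median of 0.67, which does not decide it. An exchange of genotype labels could give all 3 directions, and it stays open because no value per exon was used here.

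Choroid plexus genes were higher in the groups labelled knockout after injury, with saline and with desipramine. A genotype difference present in every condition would raise the list in naive mice too. There the list median was -0.76 (95% bootstrap interval over genes -0.94 to -0.49), with 0 of 14 positive and 0 called by Cuffdiff. The naive direction goes against that explanation. The interval redraws genes and not mice, so it leaves out the spread between samples and does not exclude it. Choroid plexus tissue carried along in the dissection stays open, because only 2 groups lie outside both injury comparisons, too few for a correlation of the list with Ttr that does not repeat the pattern itself. Ttr ran from 13.4 FPKM with desipramine to 1390 in naive mice among the groups labelled wild type and from 406 to 641 among those labelled knockout, and 8 of the 14 list genes had an FPKM of at least 1 in every group. A change within the choroid plexus that depends on genotype and injury was not tested, and lane and group remain confounded.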

How the results depend on the processing

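The normal p without centring on genes with a recovered standard error, standard errors from the deposited p and the counts without marker lists or without genes that follow a tissue index were chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per group, and for the same reason the replicate block and leaving out each replicate were not run. Depth is unknown, so its limits could not be given. Comparisons are given in the order naive, saline and desipramine genotype differences, injury in mice labelled wild type and knockout, and desipramine in the same.

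Counts of called genes stayed within 1.5 times with an FPKM filter, adjustment over all 7 tables, a minimum log2 fold change of 0.5 and without neighbouring-tissue marker lists, in all 7 comparisons. The minimum fold change could remove no call in the naive and saline genotype differences or in injury and desipramine in mice labelled wild type. The smallest called absolute log2 fold changes there were 0.809, 0.570, 0.792 and 0.528. The marker lists hold only 11, 15, 14, 8 and 11 genes. Leaving them out could not move counts of 250, 248 and 181 past 1.5 times, so it says little about tissue there. At q of 0.01 or less Cuffdiff left 114, 0, 106, 114, 0, 0 and 117 genes. The zeros come from the floor that Cuffdiff sets on p, since genes at that floor had a q above 0.01 in those tables, and 501, 758 and 310 genes had an unadjusted p under 0.05 there. A normal p from the statistic called 77, 53, 86, 86, 65, 54 and 78 genes. Of these, 39, 35, 41, 38, 42, 39 and 41 had a normal p below 1e-04 but a deposited p above 0.05, and 27, 12, 36, 32, 16, 12 and 33 were among the deposited calls. On genes with a recovered standard error, which leaves the former out, a normal p called 29, 16, 39, 32, 20, 11 and 27, of which 19, 12, 30, 22, 13, 8 and 23 were among the deposited calls. Centring the fold changes as well gave 28, 16, 39, 26, 20, 11 and 28, so most of the fall came from the normal p and the genes left out. The split of higher and lower, centred or not, was 19 and 20 against 54 and 95 deposited for the desipramine genotype difference, 10 and 10 against 50 and 29 for injury in mice labelled knockout, and 8 and 3 against 29 and 6 for desipramine in mice labelled wild type. Without genes that follow a cortical, choroid plexus or hypothalamic index the counts were 156, 23, 71, 164, 51, 13 and 60. Of called genes with an FPKM of at least 1 in a group 39.6, 59.2, 49.6, 35.3, 35.5, 60.7 and 62.5 percent followed an index, against 31.7, 53.6, 42.2, 29.6, 60.02, 52.0 and 49.4 percent of tested genes at that level.

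Of the 36 list results, all 36 passed with a background of FPKM of at least 1. With calls at q of 0.01 or less 21 passed, but 12 of the 15 losses lie in the 3 tables where no q reached 0.01 and say nothing. The other 3 were pericyte genes in naive mice, septal and hypothalamic genes with injury in mice labelled wild type, and cortical genes with desipramine in mice labelled knockout. With a deposited p of 0.01 or less 67 passed, keeping 31, losing 5 and gaining 36. The 5 were interneuron and septal genes in the desipramine genotype difference, neuropeptide and septal genes with injury in mice labelled knockout, and pericyte genes with desipramine in mice labelled knockout. Enrichment beside Rgs9 was absent at 5 and 20 Mb, and at a q of 0.01 or less in naive and desipramine-treated mice, the saline table having no gene at that q. Of 140 named genes, counted per comparison, 5 lost the call when adjusted over all 7 tables, 62 with a normal p and 75 with centred fold changes and a normal p, none with the FPKM filter, and none reversed under these alternatives.

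With an FPKM of at least 5 in all groups, 6 and 7 genes differed between the injury and the desipramine responses of the genotypes, 8 and 7 between the genotype differences, and 13 between injury and desipramine in mice labelled knockout. With standard errors from the deposited p the first 4 of these were 91, 44, 101 and 58, and injury against desipramine gave 180 and 161 in mice labelled wild type and knockout. With no FPKM filter the Pearson correlation turned to -0.0215 for the injury responses and to -0.0693 for the genotype differences in naive and saline-treated mice, and the cause was not tested. The cause of the other changes above was not tested, except where stated.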

Other observations

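Of the lists, 12 had no call in any of the 7 tables. Astrocyte genes gave 3 of 84 tests with an unadjusted Cuffdiff p under 0.05 over the 7 tables, microglia genes 7 of 98, oligodendrocyte genes 9 of 91, oligodendrocyte precursor genes 4 of 63 and endothelial genes 6 of 77. The oligodendrocyte genes moved to 1 side in several tables: besides the desipramine comparisons given above, 0 of 13 were positive in the saline genotype difference (median -0.17), 12 of 13 with injury in mice labelled wild type (0.28) and 13 of 13 with desipramine in mice labelled knockout (0.10). Cuffdiff called 0 of them in these 3 comparisons, and 1, 1 and 0 had an unadjusted p under 0.05. Cytokine and inflammatory genes gave 8 of 149, interferon-stimulated genes 6 of 128, genes of histone deacetylases and other chromatin regulators 6 of 230, circadian clock genes 6 of 133, and heat-shock genes 10 of 161. Of the RGS family and its partners, 3 of 119 tests were called, all of them Rgs9. Monoamine genes were called higher 3 times and lower 5 times in 214 tests, among them Drd1a, which encodes the D1 dopamine receptor, at 39.0 to 70.0 FPKM (log2 fold change 0.84) from the naive group labelled wild type to that labelled knockout in the authors' deposited table. Of the opioid list 1 of 56 tests was called, the nociceptin precursor gene Pnoc, which rose with desipramine in mice labelled knockout from 4.77 to 9.03 FPKM (log2 fold change 0.92) in the authors' deposited table.

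The small nuclear RNA 7SK stood at 138 FPKM in the naive group labelled knockout and 4.50 in the naive group labelled wild type (log2 fold change 4.94) in the authors' deposited table. In mice labelled knockout it was listed at 2.52 after injury with saline (-5.77) and at 39.0 with desipramine (3.93). Lars2 and Hyal1 were high in the same 2 groups, with Lars2 at 109 and 182 FPKM against 19.4 to 30.9 in the other 4 groups, and Hyal1 at 34.2 and 15.4 against 1.44 to 1.98, on levels set across tables by 1 factor per table. These 3 genes were picked out together after their values were seen, and whether library preparation plays a part was not tested. Mitochondrially encoded genes, of which 3 were tested, had a list median of 0.65 in the comparison of naive mice and 0.62 with injury in mice labelled wild type, with 0 of 21 tests called by Cuffdiff or under an unadjusted p of 0.05 over the 7 tables. Of the sex-linked list 0 of 28 tests were called and 1 had an unadjusted p under 0.05.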
